A study of Rattus norvegicus with 72 samples.

How the data were processed

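Lung RNA of 72 adult male Sprague-Dawley rats was measured, 1 library per animal. Per the labels' protocols, rats inhaled filtered air or an aerosol of diesel exhaust particles (DEP) at 200 or 1000 ug/m3, 6 hours per day for 4 days, and were killed 1, 7 or 27 days after the exposure ended. Total RNA came from a piece of lung, and libraries were made with a stranded total RNA kit after depletion of ribosomal RNA, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, SAMtools 1.8, HTSeq 0.6.1 and the genome build Rnor_6.0, with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be assigned with certainty, and members of multigene families may share reads.

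The authors deposited 1 table of raw read counts for 30042 gene symbols in 72 libraries, and 24383 of these genes had at least 1 count. Gene symbols were used as the table gives them. Of the 30042 symbols, 19073 matched a rat gene name table of the assembly GRCr8 directly and 2409 matched it by a synonym, while 8560 did not match. That table served only for names, and no coordinates are given because the builds differ. Groups came from the sample titles and characteristics. Air animals carry the letter H or L in their titles, as do exposed animals, where H goes with 1000 ug/m3 and L with 200 ug/m3. Each exposed group was compared with the air group of the same letter and day, so no control library served 2 of the 6 comparisons. The labels do not say what the letters mean, or whether the H and L animals were exposed or sequenced together. Animal numbers differ between all groups, and the labels pair no animals. The H animals fall into 2 series of numbers, each with air and exposed animals at every day, whose meaning the labels do not give; this series was used as a block in an alternative. Among 180 pairs of libraries within groups, 0 were identical. The smallest chi-square per degree of freedom between 2 libraries of a group was 1.27, above sampling noise. It belonged to animals 053 and 054 of air L at day 1, where the next lowest pair had 1.79. Animals 058 and 061 of the 200 ug/m3 group at day 1 had 1.31, where the next lowest pair had 2.09. Why these pairs were closer than others of their groups was not tested.

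Counts per gene were tested with edgeR 4.0.16 in R 4.3.3. TMM factors, filterByExpr by group and robust quasi-likelihood dispersions were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 24 libraries of a day entered 1 fit with a mean per group, from which both doses, their difference and the difference between the air groups were taken. Differences of an effect between days came from fits of 36 libraries per dose. Standard errors were derived from the quasi-likelihood F statistic, and intervals are 95% intervals. Levels are given as TMM-scaled CPM (counts scaled to a library total of 1e6), computed here from the deposited counts.

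Gene lists were fixed before the data were examined: 17 lists of responses and 22 of cell types, with 445 members, of which 426 were found in the table and 6 of those by a synonym. No member of the list of mitochondrially encoded RNA was found. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named were chosen by a rule fixed before the data were examined. It takes up to 10 rising and 10 falling genes per comparison that pass the test, have a gene symbol that is not an identifier, have a mean log2 CPM of at least 0 and lie on the called side in at least 5 of 6 exposed libraries. For differences between doses, days or air groups it takes up to 5 in each direction. From each described list it takes up to 4 passing members, and otherwise the member with the smallest p as a value only. For the air groups, only some of the genes that the rule takes are named. A gene that this rule names is not reported here. Which lists to describe was decided after the list tests were seen. Cyp1a1 is given in every group. Genes named outside this rule are marked as chosen after their values were seen.

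Alternatives fixed before the data were examined were RLE factors, no scaling factors, a filter of at least 1 CPM in at least 6 libraries, no filter, DESeq2 1.42.0, limma-voom, non-robust dispersions, a fit of only the 12 libraries of a comparison, a fit of all 72, a pooled air control, 1 surrogate variable from sva 3.50.0, an added fold limit of 1.5 and the animal number series as a block. Thresholds of 0.1 and 0.01 were tried for the overlap of calls. Fits without the 3 libraries below 500000 counts were added after the data were seen. The requirement that a value pass the bound of an explanation by more than its spread was set after the results were seen. The tests were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed. For 1000 ug/m3 at day 1, simulated on 12201 genes, 95.5% of the genes changed by a fold of 2 and 50% of those changed by a fold of 1.5 were recovered. At day 27, simulated on 14678 genes, the shares for 1000 ug/m3 were 83.6% and 62.1%. Recovery was lower for differences of effects: at a fold of 1.5 it was 30.8% to 43.9% for the dose differences and 26.9% to 40.3% for the changes between days. The simulation has no correlation between genes and no hidden groups of animals.

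Library totals set the precision. A count of 3 corresponds to between 0.460 and 28.4 CPM over the 72 libraries, and such floors cover counting error only.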

Results

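Gene expression was measured by RNA sequencing in the lungs of rats 1, 7 and 27 days after 4 daily inhalations of diesel exhaust particles, a combustion aerosol of soot carrying aromatic hydrocarbons. There were 12 groups of 6 animals. At each day, 6 rats had inhaled 1000 ug/m3 and 6 had inhaled 200 ug/m3, and each exposed group had its own 6 air rats, called air H for the higher and air L for the lower concentration after the letters in the sample titles. The series title names pulmonary effects of inhaled diesel particles as its subject, and the comparisons ask which lung transcripts differed after each concentration and at each time.

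The libraries of day 1 held 1042336 to 2397971 counts, those of day 7 held 3471134 to 6279763 and those of day 27 held 3761631 to 6520180, apart from 3 shallow libraries. These were 1000 ug/m3 animals: 037 at day 7 with 105453 counts, and 024 and 045 at day 27 with 439393 and 149004 counts. The day of killing and the depth therefore cannot be told apart between day 1 and the later days. At day 1 the median total was 1234767 after 1000 ug/m3 and 1619429.5 in air H, and 1499715 after 200 ug/m3 and 1469202.5 in air L.

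**Figure D1:**
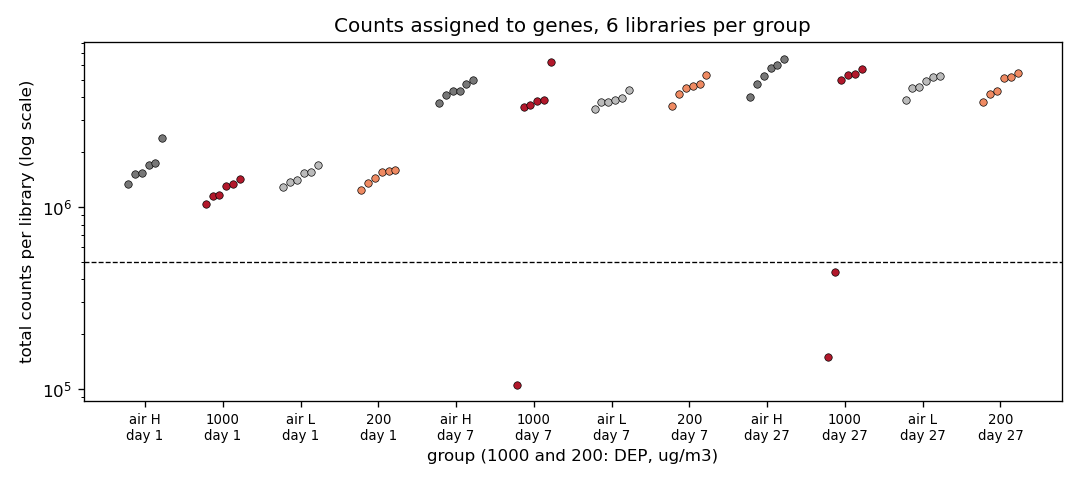
Total counts per library (log scale) in the 12 groups, each point 1 of 6 animals; the dashed line is at 500000 counts. The 3 libraries below it belong to the 1000 ug/m3 groups of days 7 and 27.

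Cyp1a1, a cytochrome P450 that the aryl hydrocarbon receptor induces after contact with combustion hydrocarbons, did not pass the test in any of the 6 comparisons of exposed with air lungs. At day 1 it stood at 15.3 ± 9.02 CPM (SD, n = 6) after 1000 ug/m3 and 18.1 ± 10.7 in air H, and at 7.05 ± 4.80 after 200 ug/m3 and 12.2 ± 5.55 in air L. At day 7 the levels were 15 ± 8.24 against 14.5 ± 10 for 1000 ug/m3, and 8.93 ± 4.67 against 14.9 ± 12.5 for 200 ug/m3. At day 27 they were 11.9 ± 13.4 against 4.43 ± 3.14 and 3.38 ± 1.01 against 7.15 ± 3.60. The log2 fold changes lay between -1.05 (SE 0.49, day 27, 200 ug/m3, adjusted p = 0.5) and 0.43 (SE 0.52, day 27, 1000 ug/m3, adjusted p = 0.905). The last value was 0.21 without the 2 shallow libraries of that group, 1 of which held its highest level, 37.9 CPM. The range within groups differed, from 3.08 to 28.9 CPM in air H of day 1 and from 1.38 to 4 CPM after 200 ug/m3 at day 27.

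**Figure D2:**
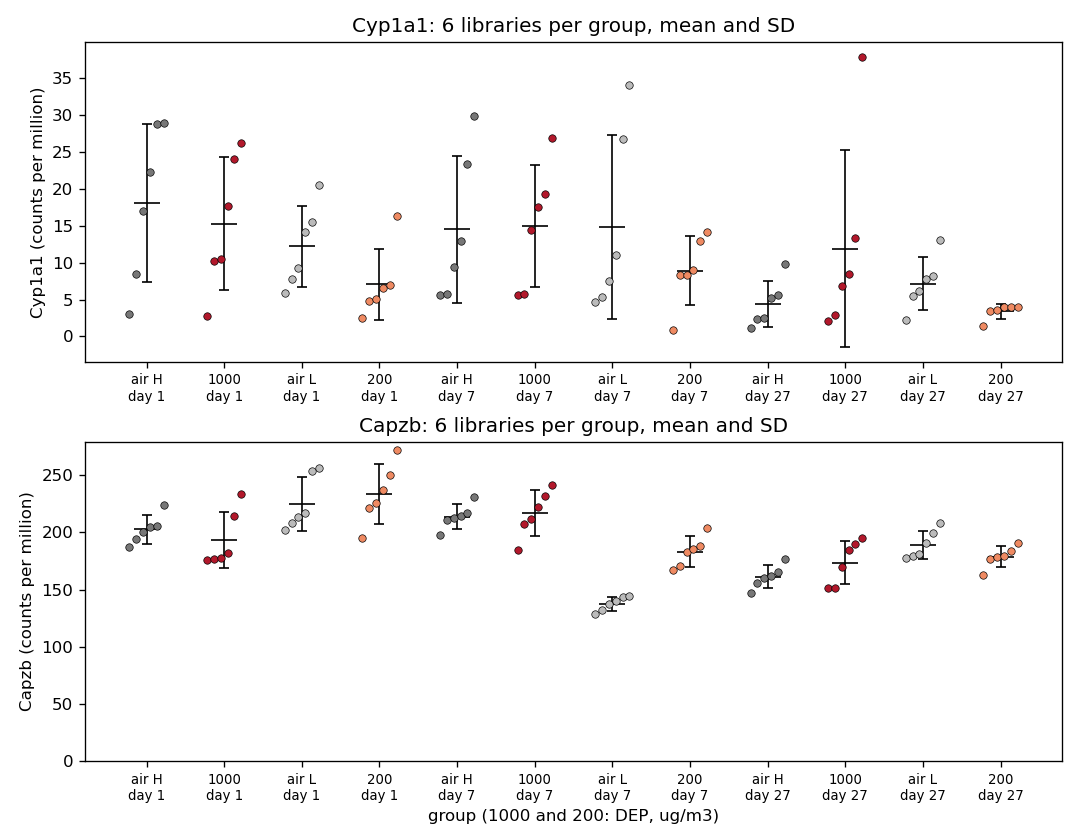
Cyp1a1 and Capzb in CPM, each point 1 of 6 animals per group, with the mean and SD. Cyp1a1 varies within exposed and air groups, least after 200 ug/m3 at day 27 (SD 1.01 CPM). For Capzb the air L animals of day 7 (128 to 144 CPM) lie below the 200 ug/m3 animals of that day (167 to 204 CPM).

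At day 1 after 1000 ug/m3, none of 12304 genes passed in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 419 genes, and DESeq2 and limma-voom called 0 each. The intervals of 96.1% of the genes excluded a change by a fold of 2 in either direction. Among the 5 tested members of the list of genes that the aryl hydrocarbon receptor induces, 0 rose or fell, and the smallest p belonged to Cyp1b1 (log2 fold change -0.21, SE 0.32). None of 11 antioxidant genes under the transcription factor NRF2 passed; Gpx2, a glutathione peroxidase, had -0.15 (SE 0.12). None of 5 chemokines and 9 cytokine or NF-kB genes passed either, with values of -0.86 (SE 0.36) for the neutrophil attractant Cxcl1 and -0.15 (SE 0.12) for Tnfaip3, an inhibitor of NF-kB. Of the 33 lists tested, camera called 6 against the remaining genes. Members of the list for cardiac muscle of the pulmonary veins were lower in 5 of 5 cases (median log2 fold change -0.50, adjusted p = 0.00536; adjusted p = 0.671 with an estimated correlation), with Myl7, an atrial myosin light chain, at -1.07 (SE 0.46). Immediate early genes were lower in 13 of 13 cases by a median of -0.15 (adjusted p = 0.0252; adjusted p = 0.807 with an estimated correlation). NK cell genes were higher in 7 of 7 cases by a median of 0.26 and xenobiotic enzymes lower in 11 of 14 by -0.10 (adjusted p = 0.0252 each; adjusted p = 0.671 each with an estimated correlation). Interferon genes were higher in 12 of 15 cases by 0.16 (adjusted p = 0.0274; adjusted p = 0.807 with an estimated correlation) and heat shock genes lower in 7 of 9 by -0.17 (adjusted p = 0.0485; adjusted p = 0.671 with an estimated correlation). Of 296 list members 0 passed over all genes, and adjusted over the list alone 1 rose, the clock gene Nr1d1 at 1.47 (SE 0.40).

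At day 1 after 200 ug/m3, none of 12304 genes passed, with 741 at an unadjusted p under 0.05 and 0 calls by limma-voom. DESeq2 called 1 gene, a fit of only the 12 libraries called 6, and a fit with 1 surrogate variable 2. The list with the smallest p was that of the genes induced by interferon, of which 14 of 15 had lower values than in air L (median log2 fold change -0.44, camera adjusted p = 9.48e-11). With an estimated correlation between the genes this call was lost (adjusted p = 0.276 with an estimated correlation). Isg15, a ubiquitin-like protein of the antiviral response, had -0.73 (SE 0.20, adjusted p = 0.627). Over all genes 0 of the 15 members passed, and adjusted over the list alone 2 fell. Air H of day 1 itself stood below air L in this list, by a median of -0.49. Proliferation genes had positive values in 8 of 9 cases (median 0.33, adjusted p = 0.01; adjusted p = 0.58 with an estimated correlation), with the spindle protein Nusap1 at 0.76 (SE 0.27). Immediate early genes were lower in 11 of 13 cases by -0.23 (adjusted p = 0.00856), interstitial macrophage genes lower in 7 of 9 by -0.22 (adjusted p = 0.0344) and cholesterol synthesis genes higher in 10 of 12 by 0.18 (adjusted p = 0.0225). For each of these 3 lists the adjusted p was 0.58 with an estimated correlation. With 1 surrogate variable the calls of proliferation, immediate early and interstitial macrophage genes were lost (adjusted p = 0.0551, 0.0787 and 0.118). Neither the aryl hydrocarbon receptor list nor the NRF2 list was called, and their members with the smallest p were Tiparp at 0.31 (SE 0.12) and Hmox1, heme oxygenase, at -0.49 (SE 0.21).

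At day 7 after 1000 ug/m3, none of 14331 genes passed. There were 629 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The intervals of 95% of the genes excluded a fold of 2. Camera called 3 of 35 lists, all higher. Acute phase and complement genes were higher in 12 of 12 cases, by a median of 0.19 (adjusted p = 0.0031; adjusted p = 0.579 with an estimated correlation), with Lcn2, the iron-binding lipocalin of inflamed epithelium, at 0.56 (SE 0.23). Type II pneumocyte genes were higher in 9 of 12 cases by a median of 0.11 (adjusted p = 0.00399), with Sftpa1, a surfactant protein, at 0.23 (SE 0.10), and B cell genes in 7 of 8 cases by 0.20 (adjusted p = 0.00399), with the IgE receptor Fcer2 at 0.76 (SE 0.25). For each of these 2 lists the adjusted p was 0.579 with an estimated correlation. Without the shallow library of animal 037 the type II call was lost (adjusted p = 0.0644) and ciliated cell genes were called (adjusted p = 0.0199). No neutrophil or alveolar macrophage marker passed; Cxcr1 had 0.34 (SE 0.24) and the lipid transporter Abcg1 had 0.18 (SE 0.10).

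At day 7 after 200 ug/m3, 1 of 14331 genes passed. Capzb, which encodes the beta subunit of the actin capping protein, was higher than in air L in 6 of 6 exposed animals (log2 fold change 0.41, SE 0.06, adjusted p = 0.000612). Its level was 183 ± 13.3 CPM (SD, n = 6) after exposure and 138 ± 6.29 in air L. Air L of day 7 had the lowest mean of the 12 groups, the other 10 lying between 161 and 234 CPM, and against a pooled air control the log2 fold change was 0.07 with an adjusted p of 0.82, where the other alternatives with a p gave 5.1e-08 to 0.0153. An added fold limit of 1.5 ended the call as well. At an unadjusted p under 0.05 there were 818 genes. DESeq2 called 5 genes, Capzb among them. Genes induced by interferon again had lower values than in air L, in 15 of 15 cases (median -0.45, camera adjusted p = 7.76e-16; adjusted p = 0.333 with an estimated correlation). Mx1, an antiviral GTPase, had -0.86 (SE 0.25, adjusted p = 0.6). Over all genes 0 of the 15 passed, and adjusted over the list alone 10 fell. Smooth muscle genes were higher in 7 of 8 cases (median 0.22, adjusted p = 0.00867; adjusted p = 0.671 with an estimated correlation), with Myh11, smooth muscle myosin, at 0.24 (SE 0.10). Proliferation genes (13 of 16 lower, median -0.17), B cell genes (8 of 8 lower, -0.23), type II pneumocyte genes (10 of 12 lower, -0.08) and glucocorticoid-responsive genes (9 of 10 higher, 0.31) were called at an adjusted p of 0.0473 each, with an adjusted p of 0.671 each with an estimated correlation. Without the shallow library of that day, which belongs to the other dose, these 4 calls were lost (adjusted p of 0.0512 to 0.0522).

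At day 27 after 1000 ug/m3, none of 14761 genes passed, with 1034 at an unadjusted p under 0.05. DESeq2 called 6 genes, limma-voom 0, non-robust dispersions 2 and a block on the animal number series 1. Camera called 7 of 35 lists. Ciliated cell genes were higher in 12 of 12 cases (median 0.39, adjusted p = 6.06e-08; adjusted p = 0.555 with an estimated correlation), and adjusted over the list alone 5 rose. The member with the smallest p was Tppp3, a tubulin-binding protein, at 0.31 (SE 0.08, adjusted p = 0.459). Club cell genes were higher in 7 of 7 cases (median 0.41, adjusted p = 0.00241; adjusted p = 0.585 with an estimated correlation), with the retinal dehydrogenase Aldh1a1 at 0.29 (SE 0.08). Both lists mark the airway lining, and in air H of day 27 both stood below air L. Immediate early genes were lower in 13 of 13 cases (median -0.29, adjusted p = 1.67e-07; adjusted p = 0.555 with an estimated correlation), with Fos at -0.89 (SE 0.30). Red blood cell genes were lower in 7 of 7 cases (median -0.36, adjusted p = 0.0122; adjusted p = 0.585 with an estimated correlation), with the anion exchanger Slc4a1 at -1.28 (SE 0.40), a gene that stood 1.79 (SE 0.39) higher in air H than in air L. Xenobiotic enzymes were higher in 11 of 14 cases by 0.10 (adjusted p = 0.0364), neutrophil genes lower in 6 of 7 by -0.31 (adjusted p = 0.034) and mesothelial genes lower in 5 of 6 by -0.41 (adjusted p = 0.0364). For each of these 3 the adjusted p was 0.585 with an estimated correlation. Without the 2 shallow libraries 0 genes passed in edgeR, with 997 at an unadjusted p under 0.05.

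At day 27 after 200 ug/m3, none of 14761 genes passed, with 1430 at an unadjusted p under 0.05. DESeq2 called 11 genes and limma-voom 0. Camera called 9 of 35 lists, 7 lower and 2 higher. Macrophage lysosome and lipid-handling genes were lower in 11 of 14 cases (median -0.20, adjusted p = 0.000138; adjusted p = 0.62 with an estimated correlation), with Mmp12, macrophage elastase, at -1.06 (SE 0.32). Proliferation genes were lower in 15 of 15 cases (median -0.36, adjusted p = 0.000138; adjusted p = 0.62 with an estimated correlation), with the cyclin Ccna2 at -0.56 (SE 0.21). Acute phase and complement genes were lower in 11 of 12 cases (median -0.24, adjusted p = 0.000568; adjusted p = 0.62 with an estimated correlation), with complement factor B, Cfb, at -0.33 (SE 0.09). B cell genes were higher in 8 of 8 cases (median 0.33, adjusted p = 0.00981; adjusted p = 0.628 with an estimated correlation). Heat shock genes were lower in 7 of 9 cases by -0.32 (adjusted p = 0.00981; adjusted p = 0.62 with an estimated correlation), and adjusted over the list alone 5 fell and 1 rose. Interferon genes (15 of 17 lower, median -0.14, adjusted p = 0.0139), alveolar macrophage genes (8 of 10 lower, -0.20, adjusted p = 0.02), cholesterol synthesis genes (12 of 13 lower, -0.14, adjusted p = 0.0215) and smooth muscle genes (8 of 8 higher, 0.16, adjusted p = 0.02) had an adjusted p of 0.628 each with an estimated correlation.

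**Figure D3:**
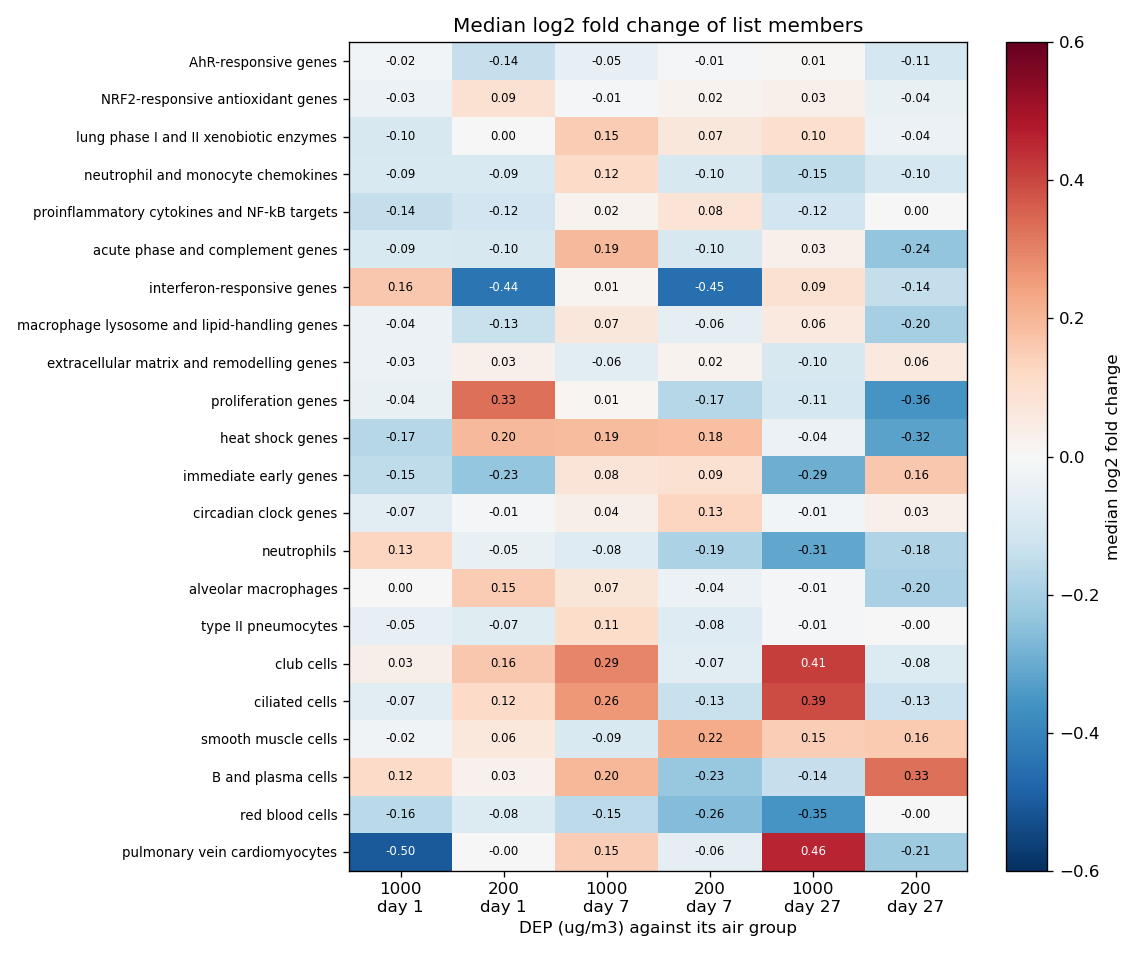
Median log2 fold change of the tested members of 22 gene lists (vertical axis) in the 6 comparisons of exposed with air lungs (horizontal axis). The values furthest below 0 are those of cardiac muscle genes at day 1 after 1000 ug/m3 (-0.50) and of interferon genes at days 1 and 7 after 200 ug/m3 (-0.44 and -0.45).

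Across the 6 comparisons, camera at its preset correlation called 36 list tests, and with an estimated correlation or with fry it was 0. The lists of chemokines, of cytokines and NF-kB targets, of NRF2 genes and of aryl hydrocarbon receptor genes were called in none of the 6. No gene was called in more than 1 comparison. Correlations of the fold changes across genes, which are not independent replicates, lay between -0.16 and 0.17 (Pearson's r) and between -0.24 and 0.20 (Spearman's rho) over the 15 pairs of comparisons. The lowest rho was that between the 2 doses of day 27.

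The difference between the doses was tested directly. At day 1 it passed for 1 of 12304 genes, Adcy1, a brain-type adenylyl cyclase (log2 difference 1.60, SE 0.27, adjusted p = 0.00685). Adcy1 stood at 35.7 ± 13.1 CPM (SD, n = 6) after 1000 ug/m3 and 20.1 ± 2.27 in air H, and at 18.3 ± 3.73 after 200 ug/m3 and 30.8 ± 5.59 in air L. Neither effect passed alone (log2 fold change 0.87, SE 0.19, adjusted p = 0.451, and -0.73, SE 0.19, adjusted p = 0.554). In a fit of all 72 libraries the difference did not pass, at 1.60 with an adjusted p of 0.343, where the other alternatives gave 0.000154 to 0.0063. At days 7 and 27 the doses differed in 0 genes, with 747 and 1961 at an unadjusted p under 0.05; DESeq2 called 1 and 34. The change of an effect between days passed for 0 genes in each of the 6 tests, with 415 to 1236 genes at an unadjusted p under 0.05. DESeq2 called 0 to 12 in these tests.

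The 2 sets of air lungs were compared at each day. Air H and air L of day 1 differed in 207 of 12304 genes (102 higher and 105 lower in H). Interferon genes were lower in air H in 14 of 15 cases, and 3 of them passed: Oasl (log2 fold change -1.02, SE 0.21), Oas1a (-0.90, SE 0.20) and Irf7 (-0.82, SE 0.21). The list median was -0.49 (camera adjusted p = 4.36e-08; adjusted p = 0.364 with an estimated correlation). The chaperones Hsph1 (0.58, SE 0.12) and Hspa8 (0.48, SE 0.10) and the flavin monooxygenase Fmo2 (0.63, SE 0.11) were higher in air H, while Terc, the telomerase RNA, was lower (-2.13, SE 0.52). DESeq2 called 446 genes, the filter at 1 CPM gave 129 calls, and the fit of all 72 libraries called 1016.

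At day 7 the air sets differed in 3653 of 14331 genes, 1479 higher and 2174 lower in H. The largest falls included the ribosomal protein gene Rps16 (-4.35, SE 0.23), the small GTPase gene Rab27a (-2.40, SE 0.13) and the extracellular matrix protein gene Ecm1 (-2.40, SE 0.11). Rps16 has near-identical copies, so its count is uncertain. Of 12 type II pneumocyte genes 4 fell and 0 rose, among them Nkx2-1 at -0.64 (SE 0.10) and Slc34a2 at -0.51 (SE 0.08), and camera did not call the list (median -0.20, adjusted p = 0.151; adjusted p = 0.966 with an estimated correlation). Of 7 neutrophil genes 2 rose, S100a8 (1.05, SE 0.29) and S100a9 (0.87, SE 0.29), and this list was not called either (median 0.13, adjusted p = 0.748; adjusted p = 0.966 with an estimated correlation). Camera called 0 of 35 lists and fry 7. Between the exposed sets of day 7, 1000 against 200 ug/m3, 4001 genes were called, of which 2528 were also called between the air sets and 2527 of those in the same direction. At days 1 and 27 edgeR called 0 genes between the exposed sets, with 1536 and 1086 at an unadjusted p under 0.05.

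At day 27 the air sets differed in 2071 of 14761 genes, 1317 higher and 754 lower in H. Matrix genes were higher in H in 13 of 14 cases, and 6 of them rose while 1 fell, with Col5a1 at 0.40 (SE 0.08), Fn1 at 0.58 (SE 0.14) and elastin, Eln, at 0.53 (SE 0.13). The list median was 0.32 (adjusted p = 0.000695; adjusted p = 0.832 with an estimated correlation). Ciliated cell genes were lower in H in 12 of 12 cases, 4 of which passed, with Foxj1, the ciliogenesis factor, at -0.54 (SE 0.17) and Dynlrb2 at -0.64 (SE 0.17). The list median was -0.39 (adjusted p = 0.000789; adjusted p = 0.986 with an estimated correlation). Club cell genes were lower in 7 of 7 cases and 4 passed, with Scgb3a2 at -0.70 (SE 0.19); the list median was -0.56 (adjusted p = 0.00863; adjusted p = 0.986 with an estimated correlation).

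**Figure D4:**
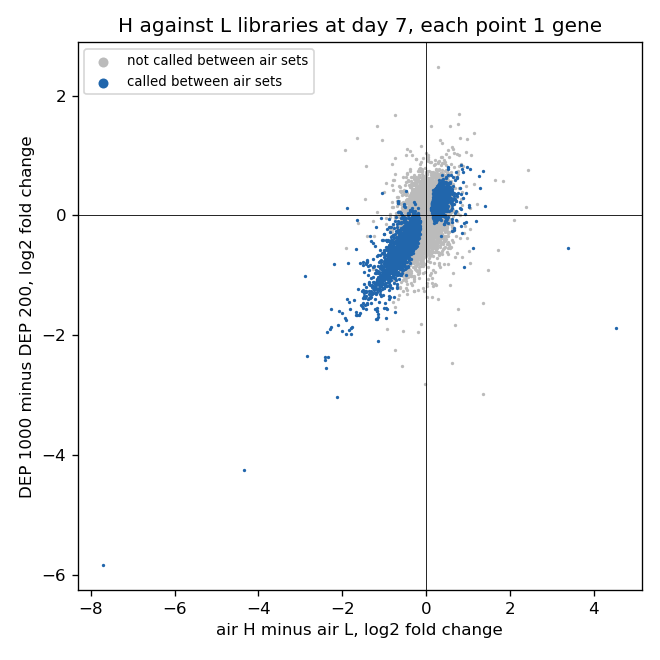
Log2 fold change of air H against air L (x axis) and of 1000 ug/m3 against 200 ug/m3 (y axis) at day 7, each point 1 of 14331 genes; no library enters both axes. Genes called between the air sets (blue) lie mostly in the quadrants of equal sign, 3555 of 3653.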

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

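The outliers and the difference of Adcy1 were found by rules set before the data were examined; the tests of explanations, other groupings of the libraries included, were chosen after the results were seen, apart from the fits to thinned counts and the smallest list p over other groupings.

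Library totals, Cyp1a1, Capzb and Adcy1 in 12 groups gave 48 groups of values tested for an animal far from the rest. Of these 3 held one, near the rate of about 1 in 20 that chance gives. All 3 concerned Cyp1a1, so the rate over all 48 groups says little about that gene alone. The rule did not flag the totals of the 3 shallow libraries, so it can miss animals far from the rest. Animal 060 of the 200 ug/m3 group at day 1 had 16.3 CPM where the other 5 had 2.54 to 6.99. Animal 045 of the 1000 ug/m3 group at day 27, a shallow library, had 37.9 CPM from 6 counts, where the others had 2.09 to 13.4 CPM. Animal 089 of the 200 ug/m3 group at day 27 had 1.38 CPM where the others had 3.47 to 4.00. The effect on Adcy1 at day 1 differed between the doses, by 1.60 on the log2 scale in the test of the difference. Of 100 groupings of the same libraries, the real one included, 5 gave 1 call or more. The highest of the others gave 1, so chance cannot be excluded. Adcy1 was also lower in air H than in air L of day 1 (log2 fold change -0.63, SE 0.19, edgeR adjusted p = 0.064). The 1.60 therefore rests in part on the air groups. An effect of the exposure and a difference between the air groups cannot be told apart.

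A count of 0 is reached by every grouping, so the 100 of 100 at days 1, 7 and 27 after 1000 ug/m3 say nothing about chance, and the same holds for each count of 0 that follows. The highest others were 7, 61 and 5. After 200 ug/m3 the counts of 0 at days 1 and 27 were reached by 100 of 100, with highest others of 57 and 5. Single groupings with 57 or 61 calls, where the median grouping gave 0, may reflect a structure among the animals or a few extreme libraries, and neither was tested. The dose differences at days 7 and 27 (0 genes) were reached by 100 of 100, with a highest other of 1 each. For the 6 changes of an effect between days, all at 0 genes and reached by 100 of 100, the highest others were 8, 2 and 6 for 1000 ug/m3 and 226, 20 and 5 for 200 ug/m3 (days 1 to 7, 1 to 27 and 7 to 27). The overlap between comparisons was 0 in all 100, and with 1 gene called in the 6 comparisons it had to be 0 for the real labels, so it says nothing about shared responses. The 36 list calls were reached by 40 of 100 groupings, and the highest other gave 52, so list calls at the preset correlation came as often without the exposure labels.

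Air H and air L differed in 207, 3653 and 2071 genes at days 1, 7 and 27. At each day 1 of 100 groupings of the 12 air libraries gave as many, the real one (highest others 78, 2077 and 9). Chance is therefore unlikely, though 100 groupings cannot exclude it. At an unadjusted p under 0.05, other groupings of day 1 with 2450 and 2457 genes exceeded the real one with 2440. All libraries of a day were then thinned to 1 total, with the shallow ones left out. At day 7, 3412 genes were called against 3877 before, 3285 of them in both. At day 27 it was 1880 against 2362, 1721 of them in both. This argues against library size as the whole cause at days 7 and 27. At day 1, 109 against 207, 75 of them in both, leave it open, because thinning also lowers power. The median totals of the air sets at day 1 were 1619429.5 in H and 1469202.5 in L. The exposed sets share no library with the air sets. Of the genes called between the air sets, 93.2% (day 1), 97.3% (day 7) and 74.5% (day 27) had the same sign in the exposed sets. The shares at days 1 and 7 go with a difference shared in direction. Day 27 lay between the bounds for this reading and does not decide it. These bounds were set after the data were seen. No other groupings were scored for these shares, so how high they come by chance was not tested. A difference of the same size in both is not shown at days 1 and 27: edgeR called 0 genes between the exposed sets (1536 and 1086 at an unadjusted p under 0.05), and the genes called between the air sets had medians of 0.209 in exposed against 0.498 in air lungs at day 1 and 0.068 against 0.344 at day 27, where picking called genes raises the air value. Batches of library preparation or counting and separate cohorts of animals cannot be told apart, since each may follow the letter and the labels do not say. No biological explanation was tested.

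Genes induced by interferon had lower values after 200 ug/m3 than in air L at days 1 and 7; 2 and 4 of 100 groupings gave a median as far from 0 (0.438 and 0.453, highest others 0.486 and 0.498). These lists were picked from all those tested, and 10 of 100 groupings gave some list in some comparison a p as small as the smallest here, 2.22e-17, the smallest of the others being 3.27e-23, so chance cannot be excluded for the set of lists. Left out 1 at a time, no animal carried the difference alone. Each of the 2 groups of day 1 held a pair of unusually close libraries, animals 053 and 054 in air L and 058 and 061 after 200 ug/m3. No pair was left out together, so a pair that carried the difference at day 1 would not show. From group means of log2 CPM instead of the fit, the medians over all animals were -0.406 at day 1 and -0.437 at day 7. Leaving out the animal that mattered most left -0.306 and -0.378 by this measure, which the next values share. At day 1 the exposed animals did not lie below air H (0.036), while at day 7 they did (-0.439). Both values set an L group against an H group. Since the H and L sets differ from each other, they cannot tell whether the air L animals were raised. An effect of the exposure stays open, as untested.

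Capzb at day 7 after 200 ug/m3 was 1 call, and 5 of 100 groupings gave as many, with 2 in the highest other, so chance cannot be excluded. Air L of that day, at 137.6 CPM, lay below the other 10 groups, of which the lowest had 161.2 CPM, but these differed by day and set by more than the difference in question, so low air L animals and a raised exposed group cannot be told apart. The exposed sets differed the same way as the air sets but less (0.257 against 0.612 on the log2 scale), and the SE of 0.057 does not place that value clearly under the bound set for a difference shared by both sets, so this stays open too. An effect of the exposure stays open, as untested.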

How the results depend on the processing

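The fits without shallow libraries and the comparison of air lungs between days were chosen after the data were seen, and all other alternatives before the data were examined. No paired analysis was possible because the labels pair no animals. The cause of each change below was not tested unless stated.

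After 1000 ug/m3 the count of 0 genes held at days 1 and 7 in all alternatives. At day 27 DESeq2 called 6, non-robust dispersions 2 and the number series as a block 1. After 200 ug/m3 at day 1 DESeq2 called 1, the 12 libraries alone 6 and 1 surrogate variable 2. At day 7, against 1 reported, DESeq2 called 5, all 72 libraries 4, a pooled air control 0 and a fold limit of 1.5 0. At day 27 DESeq2 called 11. The dose difference at day 1 went from 1 to 2 with DESeq2 and 0 with all 72 libraries, that at day 7 from 0 to 1 with each, and that at day 27 from 0 to 34 with DESeq2 and 22 with all 72 libraries. Among changes between days, DESeq2 called 1 for 1000 ug/m3 from day 7 to 27, and 7 and 12 for 200 ug/m3 from days 1 and 7 to 27, where all 72 libraries gave 2 for days 7 to 27. Air H against air L at day 1 went from 207 to 129 with the filter at 1 CPM, 446 with DESeq2 and 1016 with all 72 libraries. The list calls went from 36 to 0 with an estimated correlation and 0 with fry. They came to 33 without shallow libraries, with those for 200 ug/m3 at day 7 going from 6 to 2, and to 36 with 1 surrogate variable, with those for 200 ug/m3 at day 1 going from 5 to 2. Air lungs of day 27 against day 1 went from 1712 to 422 and from 5045 to 2170 genes when thinned, where each library holds fewer counts. For the overlap of calls no alternative moved the count of 0.

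For named genes, 2224 values under alternatives kept their side of the threshold, 52 no longer passed it and 1 newly passed it (Sftpa1 at day 27 after 200 ug/m3 with DESeq2, -0.37, adjusted p = 0.0461). Direction was checked only where the reported or the alternative value passed, so values that passed in neither may have changed sign. Depth limits low genes in the 3 shallow libraries, where a count of 3 is 6.83 to 28.4 CPM, and at day 1, where it is 1.25 to 2.88 CPM.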

Other observations

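The comparison of air lungs between days was chosen after the data were seen, as were its alternatives and the genes named here. In air lungs, genes of the extracellular matrix were lower at day 27 than at day 1 in both sets. Of 14 list members tested, 10 fell in air H and 11 in air L, and 0 rose (edgeR, 6 against 6 libraries). The list medians were -0.42 and -0.69 on the log2 scale, and camera called both also with an estimated correlation (adjusted p = 0.00118 and 0.000587 with an estimated correlation). Elastin, Eln, fell by 1.29 (SE 0.12) in air H and by 1.85 (SE 0.12) in air L, the collagen gene Col1a1 by 1.44 (SE 0.21) and 2.49 (SE 0.23), and the collagen-binding protein gene Sparc by 0.50 (SE 0.07) and 0.70 (SE 0.07). Of 8 smooth muscle genes 1 fell in air H, where the list was not called (adjusted p = 0.0682; adjusted p = 0.669 with an estimated correlation), while 5 fell and 1 rose in air L (median -0.57, adjusted p = 0.00863; adjusted p = 0.76 with an estimated correlation). NK cell genes were higher at day 27, with 5 of 9 members rising in each set; the list was called in air H (median 0.72, adjusted p = 5.21e-05; adjusted p = 0.253 with an estimated correlation) and not in air L (0.64, adjusted p = 0.153; adjusted p = 0.946 with an estimated correlation). Nkg7, a cytotoxic granule protein, rose by 0.76 (SE 0.19) and 0.59 (SE 0.19). Beside these, 2 of 8 red blood cell genes fell in air H (median -0.60, adjusted p = 0.00541; adjusted p = 0.669 with an estimated correlation) and 6 of 8 in air L (-1.20, adjusted p = 0.00617; adjusted p = 0.881 with an estimated correlation). Immediate early genes were higher in air H (0.39, adjusted p = 0.0103; adjusted p = 0.669 with an estimated correlation). Heat shock genes (0.65) and xenobiotic enzymes (0.43) were higher in air L (adjusted p = 0.00617 each; adjusted p = 0.278 and 0.538 with an estimated correlation).

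Day 27 differed from day 1 in 1712 genes in air H (703 higher and 1009 lower) and in 5045 genes in air L (2350 higher and 2695 lower). Of the 1068 genes called in both sets, 1031 moved the same way, 327 up and 704 down, where independent lists would share 113.3 and 186.6. The lists are not independent, since both came from 1 fit with shared dispersions and set shallower against deeper libraries. The excess alone therefore does not show a shared effect of time. Among 100 groupings of the day labels, 1 gave as many calls in each set, the real one, with highest others of 24 and 2766. With all air libraries thinned to the total of the smallest, 422 and 2170 genes were called. Of these, 381 and 2105 were among the genes called without thinning. The animals of day 27 were killed later after the exposure and their libraries were deeper than those of day 1, and the labels do not say whether the days were prepared together, so time and library batch cannot be told apart.

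The number of genes with an unadjusted p under 0.05 for the difference between doses at day 27, 1961, was not reached by any other of 100 groupings, of which the highest gave 1496 and the median 530.5, although 0 genes passed after adjustment. This count was 1 of 9 compared with other groupings in this way, and the air sets of day 27 differed from each other.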
